A study of Mus musculus with 15 samples.

How the data were processed

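The series holds 15 single-colour oligonucleotide arrays of total RNA from mouse macrophages that were grown from bone marrow in macrophage colony-stimulating factor. The cells were wild type or carried a floxed Junb gene together with Cre recombinase in both copies of the Lyz2 locus, a myeloid-cell gene that encodes lysozyme. They were left untreated or given lipopolysaccharide (LPS), the cell wall component of Gram-negative bacteria, at 100 ng/ml, and RNA was taken after 4 h. There were 4 untreated and 4 LPS arrays of wild type cells and 4 untreated and 3 LPS arrays of knockout cells. Groups and replicate numbers come from the sample titles. The labels call the replicates independent wells, so p-values measure only the spread between these wells, which may be partly technical, and not the spread between mice.

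Per the labels' protocols, RNA was amplified as aminoallyl-aRNA, coupled to Cy3 and hybridised to an Agilent mouse design with 8 arrays per slide. Per the file headers, the spots were read with Agilent Feature Extraction 10.7.3.1, and the probe design refers to the mouse build mm9. The processed signal is an intensity on a linear scale from which the software had subtracted the background, per the file headers, with no scaling between arrays. The other signals used were the median spot and median local background intensity, per the file headers uncorrected. The plan foresaw a gene name column and the mean spot signal for normexp; names by RefSeq accession and the median signal took their place, and the former were not used here. The deposited value table of the series holds log2 values. Its source and scale were inferred: each of its 15 columns ranked best with the median spot signal of its own array (lowest Spearman correlation 0.968), and the columns share nearly the same distribution, with medians between 6.25 and 6.27, as after quantile normalisation. The exact method and any background step remain unknown. The table lists 50378 of the 59305 non-control features. On at least 1 array, each of the 8927 left out had been marked by the software. The marks counted were for a non-uniform spot, a population outlier or a non-uniform local background. The probes used for Junb and Lyz2 are among those left out, so the value table served only as an alternative.

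Per array, spots marked as non-uniform or population outliers were set to missing (4827 spots over all arrays), control spots were left out, and no spot was saturated. A mark for the local background alone did not set a spot to missing. The processed signal was divided by the array's 75th percentile and then raised to a common floor, the highest of the arrays' own limits of signals well above background (0.0436 of the 75th percentile, -4.52 on the log2 scale), before log2 was taken. Values at the floor have no order. Spots of the same probe were averaged. Of 55681 probes, 28116 carry a RefSeq accession, and 26582 of these matched exactly 1 symbol in a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. The other 29099 probes stay unnamed here, and Il12b had no matched probe. A probe was kept when it was well above background on at least 3 arrays of 1 group (32522 probes, 18345 with a symbol). Each gene was represented by its kept probe with the highest mean over all arrays, which gave 14198 genes, of which 3485 had more than 1 kept probe. Of the values of these genes, 0.325% were missing.

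The 75th percentile of the signal ranged from 482 to 1490 and the share of spots well above background from 51.0% to 63.2% over the arrays. The precision is limited by the number of arrays, by the spread between them and, for dim probes, by the signal over background. All knockout arrays lay on slide 1 and all wild type arrays on slide 2, each with 1 scan. In comparisons of knockout with wild type, slide and genotype therefore cannot be told apart. The LPS comparisons lie within a slide. A constant slide effect on the log2 scale cancels in the difference between the LPS responses of genes above the floor. It does not cancel for genes at the floor in untreated cells of both genotypes, whose difference rests on the levels with LPS.

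The main model was fitted with limma 3.58.1 in R 4.3.3 (the package data.table, version 1.17.8, read the files): 4 group means over all 15 arrays, lmFit and eBayes, and Benjamini-Hochberg adjustment over all genes tested at 0.05. Fold changes are LPS over untreated, or knockout over wild type, on the log2 scale with their standard errors (SE). The contrasts were the LPS response in each genotype, the difference of these responses, and knockout against wild type without and with LPS. The equal-weight mean of both LPS responses served only to define induced and repressed genes (at least 2-fold). Where a probe was well above background on no array of a group, a fold is given as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. A gene given as measured on only some arrays of a group was well above background on those arrays. Its other arrays entered the fit with their own signal or the floor, so the size and SE can depend on the floor. Junb and Lyz2 were also compared with two-sided exact permutation tests. Across genes, the LPS responses of both genotypes were correlated; genes are not independent replicates.

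There were 27 gene lists, fixed before the data were examined: the AP-1 family, pro-inflammatory cytokines, anti-inflammatory mediators, chemokines, the NF-kB pathway and its targets, interferon-stimulated genes, classical activation effectors, alternative activation markers, MHC class II presentation, co-stimulatory and co-inhibitory ligands, Toll-like receptors and adaptors, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, cholesterol efflux and LXR targets, the cell cycle, the unfolded protein and integrated stress response, NRF2 targets and macrophage identity. Further lists hold markers of neutrophils, dendritic cells, B cells, T and NK cells, stromal cells, erythroid cells, mast cells with basophils, and osteoclasts. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 27 lists within a contrast. Genes of a list were also adjusted over the list alone.

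The genes named were chosen by a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among called genes well above background on every array of at least 1 group compared, without clone names, for the wild type LPS response, the difference and both genotype comparisons. It adds up to 2 called members with the largest rise and 2 with the largest fall per list and contrast, and always Junb, Lyz2, the other AP-1 members, Il1b, Il6, Tnf, Il10, Nos2, Arg1, Cxcl10 and Ifnb1.

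The alternatives fixed in advance were quantile normalisation, normexp background correction (offset 50, on the median spot signal in place of the mean), the deposited value table, other background filters, the mean of a gene's probes, every probe tested, outlier spots kept, saturated probes left out, only the arrays compared, trended robust eBayes, array weights, the replicate number as a block, each replicate left out, and at least 2-fold. A lower floor (0.0145), 3 wide-spread arrays left out together, and genes of X and Y left out were added after seeing the data. The model fit was tested on simulated log2 values of 14197 genes. In each comparison, 66 genes were changed by 4-fold, 67 by 2-fold and 67 by 1.5-fold. For 4-fold, 2-fold and 1.5-fold changes, the share recovered was 87.9%, 65.7% and 31.3% for the wild type LPS response, 90.9%, 76.1% and 31.3% for the knockout LPS response, and 83.3%, 32.8% and 5.97% for the difference. It was 86.4%, 68.7% and 28.4% for knockout against wild type untreated, and 83.3%, 68.7% and 20.9% with LPS. Of the simulated calls, 2.54% to 6.82% were false. The simulated noise was independent between genes, and scaling, floor, filter and choice of probe were not part of the test. Far fewer genes were changed than were called for LPS in the data, so these shares may not carry over.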

Results

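Gene expression was measured in 15 cultures of mouse bone marrow-derived macrophages to ask how the loss of Junb, which encodes a subunit of the AP-1 transcription factor, alters the resting state of these cells and their response to LPS. Knockout cells differ from wild type cells also by Cre in both copies of Lyz2 and, by the sex-linked genes described below, probably by sex. Effects of Junb loss, Cre, Lyz2 loss and sex cannot be told apart, also not in the difference of the LPS responses. Wild type cells gave 4 untreated and 4 LPS arrays, and knockout cells gave 4 untreated and 3 LPS arrays. The small number of arrays is 1 limit on precision. Correlations between arrays of the same group, across genes, ranged from 0.961 to 0.997. Around the mean of its group, the log2 value of a gene deviated with an SD of 0.627 on untreated knockout replicate 3, 0.540 on untreated wild type replicate 1 and 0.525 on LPS-treated wild type replicate 4, against 0.231 to 0.434 on the other 12 arrays.

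Junb was well above background on all wild type arrays and on 0 of the 7 knockout arrays. Its processed signal was 1291 to 2068 in untreated and 4323 to 9574 in LPS-treated wild type cells, and -0.395 to 4.15 in untreated and 0.645 to 3.71 in LPS-treated knockout cells. The knockout was at least 75.1-fold lower untreated and at least 302-fold lower with LPS, and each comparison gave the smallest two-sided exact permutation p that these group sizes allow, 0.0286. Lyz2, the lysozyme gene that carries Cre in this line, had signals of 345888 to 448164 in wild type and 869 to 3793 in knockout cells, with log2 differences of -8.24 ± 0.17 (SE) untreated and -6.96 ± 0.18 with LPS and the same exact p of 0.0286. Since the wild type signal lies near the bright end of the arrays, the sizes of these falls are uncertain. The probe of its close paralog Lyz1 was lower by -3.34 ± 0.12 and -3.05 ± 0.13 and is reported as uncertain, because the 2 transcripts are similar in sequence.

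**Figure D1:**
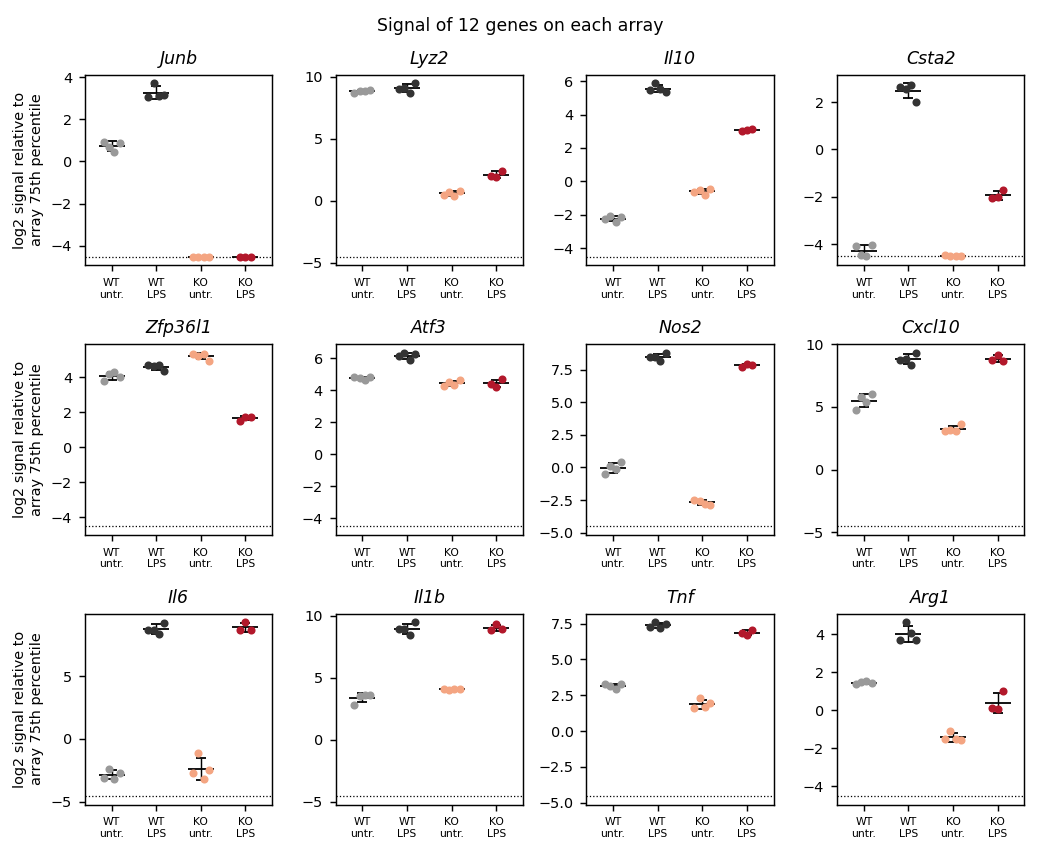
Log2 signal relative to the 75th percentile of each array (vertical axes) of 12 genes on the 15 arrays, by genotype (WT, wild type; KO, knockout) and treatment. Points are arrays, horizontal bars with whiskers the group mean ± SD, and dotted lines the floor at -4.52; Junb lies at the floor on all 7 knockout arrays, and Il10 rose less with LPS in knockout than in wild type cells.

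In wild type macrophages, LPS raised all 19 measured pro-inflammatory cytokines, 17 of 19 chemokines and all 29 interferon-stimulated genes and lowered 16 of 24 cell cycle genes within 4 h. As lists, the last pair did not pass with an estimated correlation (adjusted p = 0.162 and 0.203). The largest rises included the cytokines Il1a (log2 fold change 11.93 ± 0.29, SE, n = 4 and 4), Il6 (11.55 ± 0.36) and Csf2 (11.25 ± 0.17), tissue factor F3 (9.43 ± 0.13, another probe 5.22), histidine decarboxylase Hdc (9.23 ± 0.17), the prostaglandin synthase Ptgs2 (8.85 ± 0.23) and the chemokine Ccl7 (8.58 ± 0.17), with adjusted p of 4.9e-12 or less. Il1a and Csf2 were each well above background on 2 of the 4 untreated arrays, so their sizes depend on the floor. The size for Il6 is uncertain, since its signal with LPS was nearly constant at the bright end of the arrays. Csf3, Shisa3 and Edn1, well above background on no untreated array, were at least 1845-fold, 815-fold and 764-fold higher. The largest falls included the pro-apoptotic gene Bmf (-7.36 ± 0.42, measured on 3 of 4 LPS arrays), the stress-inducible gene Sesn1 (-6.58 ± 0.13), the chemokine receptor Cxcr4 (-5.68 ± 0.12), Engase (-5.39 ± 0.15, another probe -4.54), Gpr183 (-5.37 ± 0.20, measured on 2 of 4 LPS arrays), Tmem86a (-5.07 ± 0.17) and Fam78a (-5.01 ± 0.20).

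All 19 measured pro-inflammatory cytokines rose (camera adjusted p = 1.4e-12), among them Il1b by 5.54 ± 0.21, Tnf by 4.22 ± 0.16 and Ifnb1 by 5.19 ± 0.15. All 14 anti-inflammatory mediators rose (adjusted p = 1.3e-07), including Il10 by 7.79 ± 0.13 and the interleukin 1 receptor antagonist Il1rn by 6.83 ± 0.20. Of 19 chemokines, 17 rose and 2 did not pass (adjusted p = 3.4e-09). Cxcl1 changed by 7.99 ± 0.13 and Cxcl10 by 3.29 ± 0.26. All 19 NF-kB pathway members and targets rose (adjusted p = 8.4e-09). The adhesion molecule Vcam1 changed by 7.86 ± 0.14 (another probe 5.98) and Traf1 by 4.03 ± 0.17. Of 24 classical activation effectors, 22 rose and 2 did not pass (adjusted p = 7.3e-12). The inducible nitric oxide synthase Nos2 changed by 8.50 ± 0.18. These 5 lists also passed with an estimated correlation (adjusted p = 0.00104, 0.0279, 0.0329, 0.0165 and 0.0329, in the order given). All 29 interferon-stimulated genes rose (adjusted p = 1.2e-13, but adjusted p = 0.162 with an estimated correlation), for example the GTPase Gbp5 by 6.10 ± 0.17 and Cmpk2 by 5.53 ± 0.18 (another probe 6.92). With LPS, the signals of Il1b (313458 to 362691), Il6 (292177 to 335742) and Cxcl10 (282643 to 355032) were nearly constant over the arrays of both genotypes, among the brightest of 55681 probes, while the 75th percentile ran from 482 to 1063. Log2 values of these 3 genes with LPS therefore follow the scaling factor, so the sizes of their LPS rises in either genotype are uncertain and no genotype difference in them with LPS can be read. The same holds for Saa3 (333914 to 424231) and Rsad2 (246835 to 360970).

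Of the 12 AP-1 family genes, 10 rose, 1 fell and 1 did not pass in wild type cells (adjusted p = 0.000784, adjusted p = 0.214 with an estimated correlation). Fosl1 rose by 4.59 ± 0.18 (measured on 3 of 4 untreated arrays), Batf2 by 4.29 ± 0.21, Batf by 4.20 ± 0.15, Jdp2 by 3.44 ± 0.15, Junb by 2.54 ± 0.14, Batf3 by 1.55 ± 0.22, Atf3 by 1.39 ± 0.12 and Jun by 0.63 ± 0.17. Fosl2 rose by 2.68 ± 0.13, while another probe of the gene gave -0.58, and Jund by 0.70 ± 0.20, which became -0.094 under quantile normalisation. Fos fell by 0.91 ± 0.13, and Fosb, at 0.78 ± 0.42, did not pass (adjusted p = 0.123). Co-stimulatory and co-inhibitory ligands (8 rose, 2 fell; adjusted p = 0.00156, adjusted p = 0.203 with an estimated correlation) included Cd69 at 5.08 ± 0.14 and Pdcd1lg2 at -1.44 ± 0.14. The other fall, that of Cd80 at -2.09, is unsettled, since another probe of the gene gave 2.03. Toll-like receptors and adaptors (15 rose, 3 fell, 1 did not pass; adjusted p = 0.00292, adjusted p = 0.258 with an estimated correlation) included Tlr3 at 3.33 ± 0.23 and Irak1 at -0.91 ± 0.12. Of the unfolded protein and integrated stress response, 12 rose, 1 fell and 1 did not pass (adjusted p = 0.00156, adjusted p = 0.258 with an estimated correlation). The cystine transporter Slc7a11 changed by 5.22 ± 0.16 and Ddit4 by 4.94 ± 0.15. Of the alternative activation markers, 15 rose, 4 fell and 3 did not pass (adjusted p = 0.0195, adjusted p = 0.338 with an estimated correlation). The chemokine Ccl17 changed by 3.70 ± 0.12 (measured on 1 of 4 untreated arrays), the interleukin 4 receptor Il4ra by 3.69 ± 0.15 and arginase Arg1 by 2.57 ± 0.23. Of 18 glycolysis genes, 12 rose and 6 did not pass (adjusted p = 0.00129, adjusted p = 0.278 with an estimated correlation), with a median of 1.00, but under quantile normalisation 9 rose and 2 fell, with a median of 0.41, and the median in the deposited value table was 0.19. Of 24 cell cycle genes, 16 fell, 5 rose and 3 did not pass (adjusted p = 0.00202, adjusted p = 0.203 with an estimated correlation). The replication licensing gene Mcm7 changed by -2.22 ± 0.16 and cyclin E1, Ccne1, by 3.07 ± 0.14 (another probe 1.60).

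The other lists did not pass in wild type cells. MHC class II presentation had 6 members that rose and 3 that did not pass (adjusted p = 0.172), oxidative phosphorylation 7 that rose, 1 that fell and 19 that did not pass (adjusted p = 0.798), cholesterol biosynthesis 9 that rose, 7 that fell and 4 that did not pass (adjusted p = 0.627), and macrophage identity 5 that rose, 4 that fell and 10 that did not pass (adjusted p = 0.574). Among the last, the chemokine receptor Cx3cr1 changed by -4.58 ± 0.17 and the transcription factor Cebpa by -3.38 ± 0.16. Lyz2, at 0.24 ± 0.17, did not pass (adjusted p = 0.227), with a wild type signal of 345888 to 448164 that lies at the bright end too. Of 11 neutrophil markers 5 rose (adjusted p = 0.137), of 8 dendritic cell markers 5 rose (adjusted p = 0.140), of 7 B cell markers 1 rose and 2 fell (adjusted p = 0.246), and of 7 erythroid markers 3 rose and 1 fell (adjusted p = 0.280). The medians of MHC class II presentation, oxidative phosphorylation, cholesterol biosynthesis, NRF2 targets, macrophage identity and T and NK cell markers changed sign with the scaling, and for cholesterol biosynthesis, NRF2 targets and macrophage identity the median was positive while the test pointed down. Adjusted over the list alone, 18 chemokines, 19 Toll-like receptors and adaptors and 22 cell cycle genes passed, and the counts of the other called lists were the same.

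Over all 14198 genes, 4957 rose and 3626 fell in wild type cells (8583 called), and 4539 changed by at least 2-fold. The split between rises and falls depended on the scaling. Rises were 57.8% of the calls here, 41.4% under quantile normalisation and 42.5% in the deposited value table, and the median over all genes was 0.14 here and -0.14 under quantile normalisation, so changes of that size carry no direction of their own.

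**Figure D2:**
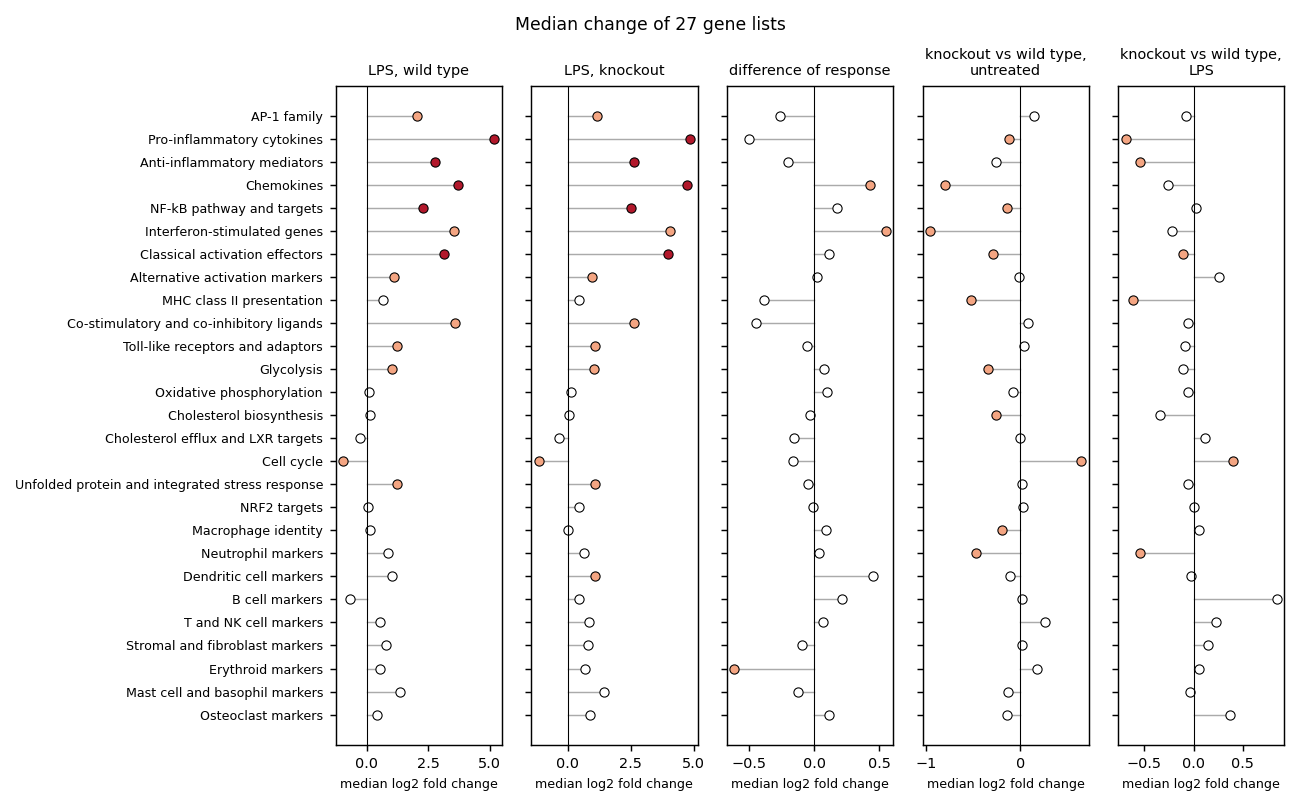
Median log2 fold change (horizontal axes) of the 27 gene lists in the 5 comparisons. Dark red points passed camera with the estimated correlation, light orange points only with the preset correlation of 0.01, and white points with neither; pro-inflammatory cytokines, with a median of 5.19 in wild type and 4.85 in knockout cells, passed both tests for LPS in both genotypes, while the medians of MHC class II presentation, oxidative phosphorylation, cholesterol biosynthesis, NRF2 targets and macrophage identity for LPS change sign with the scaling.

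Knockout macrophages also mounted a broad LPS response. Across genes, its log2 fold changes correlated with those of wild type cells (Pearson 0.885, Spearman 0.820), with no array shared between the comparisons. In knockout cells 4612 genes rose and 3898 fell (8510 called of 14197; 4499 by at least 2-fold). Of the genes that rose, 3747 rose in both genotypes, where independent lists would share 1610, and of those that fell, 3051 fell in both, against 996. Il1a rose by 11.54 ± 0.33 (measured on 1 of 4 untreated arrays), Il6 by 11.23 ± 0.39, Nos2 by 10.53 ± 0.19, the chemokine Ccl7 by 8.20 ± 0.19, Il1b by 4.97 ± 0.23, Il10 by 3.69 ± 0.14 and Arg1 by 1.82 ± 0.25, and Tnf rose as well. The sizes for Il6 and Il1b are uncertain, since their signals with LPS were nearly constant at the bright end of the arrays. Ifnb1 was at least 41.9-fold higher than in untreated knockout cells, where it was well above background on no array.

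The lists that passed in wild type cells passed in knockout cells too. Rises in 18 of 19 pro-inflammatory cytokines (adjusted p = 2.4e-12), 12 of 14 anti-inflammatory mediators (1 fell; adjusted p = 1.2e-05), 18 of 19 chemokines (adjusted p = 1.2e-11), all 19 NF-kB genes (adjusted p = 1.6e-09) and 23 of 24 classical activation effectors (adjusted p = 1.5e-13) passed also with an estimated correlation (adjusted p = 0.00121, 0.0466, 0.0237, 0.0120 and 0.0237). All 29 interferon-stimulated genes rose (adjusted p = 3.6e-16, adjusted p = 0.111 with an estimated correlation). Gbp5 changed by 7.30 ± 0.19. Of the AP-1 family, 7 rose, 1 fell and 4 did not pass (adjusted p = 0.0196, adjusted p = 0.322 with an estimated correlation). Batf2 rose by 4.47 ± 0.22, Fosl1 by 4.32 ± 0.19 (measured on 3 of 4 untreated arrays), Batf by 3.76 ± 0.16, Jdp2 by 3.20 ± 0.16, Fosl2 by 2.58 ± 0.14 (another probe 0.53), Jund by 1.22 ± 0.21 and Jun by 0.59 ± 0.18. Fos fell by 1.28 ± 0.14, and Fosb at 1.07 ± 0.45, Atf3 at -0.01 ± 0.13 and Batf3 at -0.14 ± 0.23 did not pass. Glycolysis (16 rose, 2 did not pass; 9 rose and 2 fell under quantile normalisation), co-stimulatory ligands (8 rose, 2 fell), Toll-like receptors (14 rose, 3 fell, 2 did not pass), the stress response (11 rose, 1 fell, 2 did not pass), alternative activation (16 rose, 3 fell, 3 did not pass) and dendritic cell markers (6 rose, 2 did not pass) passed upwards, and the cell cycle downwards (4 rose, 17 fell, 3 did not pass), with adjusted p of 0.000161, 0.00115, 0.00388, 0.00169, 0.00336, 0.0486 and 0.000683. With an estimated correlation these were adjusted p = 0.270, 0.144, 0.270, 0.270, 0.270, 0.138 and 0.138. Among the co-stimulatory ligands, the fall of Cd80 at -2.62 is unsettled, since another probe of the gene gave 1.24. Adjusted over the list alone, 9 AP-1 genes and 13 of the stress response passed, and the counts of the other called lists were the same. Median and test differed in sign for cholesterol biosynthesis, macrophage identity and B cell markers, none of which passed, and the scaling changed the sign of the medians of these lists and of MHC class II presentation, oxidative phosphorylation and NRF2 targets. Rises were 54.2% of the calls here, 37.5% under quantile normalisation and 35.1% in the deposited value table.

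The LPS response itself differed between the genotypes for a smaller set of genes. Among them, Il10, Zfp36l1 and Csta2 had lower and Sh2d4a, Gfi1 and F2r higher responses in knockout cells. Il10, which encodes an anti-inflammatory cytokine, rose by 7.79 in wild type and 3.69 in knockout cells, a difference of -4.10 ± 0.18 (adjusted p = 4.0e-08). Zfp36l1, which encodes an RNA-binding protein that promotes mRNA decay, rose by 0.54 in wild type and fell by 3.55 in knockout cells (difference -4.09 ± 0.20, adjusted p = 6.3e-08). Further lower responses in knockout cells were those of the protease inhibitor gene Csta2 (-4.18 ± 0.23), the cytokine Il19 (-3.73 ± 0.45), Inhba (-3.51 ± 0.26), cyclin D2, Ccnd2 (-3.44 ± 0.20), Gcnt2 (-3.39 ± 0.29), the insulin receptor substrate Irs2 (-3.29 ± 0.30), Ifi202b (-3.28 ± 0.35, another probe -3.88) and Slc28a2b (-3.08 ± 0.20, another probe -2.30). Inhba and Ifi202b were well above background on no untreated knockout array and on 1 of 4 untreated wild type arrays, and Csta2 and Gcnt2 on 1 of 4 untreated knockout arrays, so the size of their differences depends on the floor. Where a gene lies at or near the floor in untreated cells of both genotypes, as Csta2 does, the difference rests on the levels with LPS. Slide and genotype cannot be told apart in such a difference. Higher responses were those of Sh2d4a (3.92 ± 0.62), the transcription factors Gfi1 (3.50 ± 0.28), Egr2 (2.88 ± 0.36) and Spib (2.72 ± 0.51), the thrombin receptor F2r (3.21 ± 0.17, measured on 1 of 4 untreated wild type and 3 of 4 untreated knockout arrays) and the gene Inava (3.11 ± 0.45, measured on 2 of 4 untreated wild type and 1 of 4 untreated knockout arrays).

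**Figure D3:**
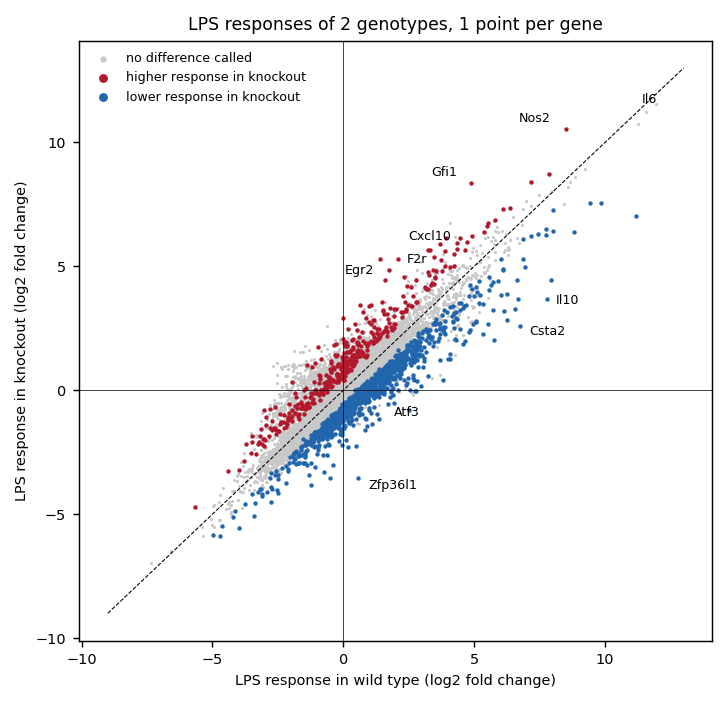
LPS response in knockout against wild type cells, both as log2 fold changes, 1 point per gene, with the dashed line marking equal responses and colours the genes whose responses differed (limma, adjusted p under 0.05). Il10 lies below the line at 7.79 and 3.69, Nos2 above it at 8.50 and 10.53, and Junb, at the floor in knockout cells, lies at 2.54 and 0.00.

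Of 29 interferon-stimulated genes, 9 had a higher and none a lower response in knockout cells (14 adjusted over the list alone; adjusted p = 7.8e-08, but adjusted p = 0.529 with an estimated correlation). The ubiquitin-like modifier Isg15 differed by 1.94 ± 0.26 (another probe 1.00). Its signal with LPS (191482 to 353038) also lies near the bright end of the arrays, so this size is uncertain. The antiviral gene Rsad2, at 1.69 ± 0.39, cannot be read as a response, since its signal with LPS was nearly constant. The list test includes both genes. Of 19 chemokines, 4 had a higher response (4 over the list alone; adjusted p = 3.5e-05, adjusted p = 0.358 with an estimated correlation), including Ccl22 at 2.39 ± 0.22, which was well above background on no untreated array, and Cxcl10 at 2.35 ± 0.38. The value of Ccl22 rests on its levels with LPS, where slide and genotype cannot be told apart. For Cxcl10 this value reflects its untreated levels (-2.29 in knockout against wild type), since its signal with LPS was nearly constant at the bright end of the arrays. Of 7 erythroid markers, 2 had a lower response (4 over the list alone; adjusted p = 0.0184, adjusted p = 0.238 with an estimated correlation). These are the carbonic anhydrase Car2, well above background on no untreated knockout array, whose difference of -2.20 ± 0.22 did not pass with a lower floor, a setting chosen after seeing the data, and the erythropoietin receptor Epor (-2.10 ± 0.17), well above background on no wild type array and on 1 of 3 LPS-treated knockout arrays, so neither size is settled.

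Members of lists that did not pass moved both ways. Among classical activation effectors (3 higher, 5 lower, 16 not passing; adjusted p = 0.967), Nos2 (2.03 ± 0.26) responded more and Edn1 (-2.43 ± 0.12, well above background on no untreated array) less, while the value of the acute-phase gene Saa3 (1.63 ± 0.29) cannot be read as a response. The value of Edn1 rests on its levels with LPS, where slide and genotype cannot be told apart. Among alternative activation markers (6 higher, 4 lower, 12 not passing; adjusted p = 0.309), the coactivator Ppargc1b (2.39 ± 0.19, measured on 1 of 4 LPS-treated wild type arrays) responded more, and Socs2 (-2.15 ± 0.19) and Il4ra (-1.19 ± 0.22, another probe -2.04) less. Among pro-inflammatory cytokines (2 higher, 6 lower, 11 not passing; adjusted p = 0.156), Tnfsf9 (1.41 ± 0.20) and Tnf (0.78 ± 0.23, adjusted p = 0.0478) responded more and oncostatin M, Osm (-2.98 ± 0.29) less, while Il1b (-0.57 ± 0.31) and Il6 (-0.32 ± 0.53) did not pass and cannot be read, given their nearly constant signals with LPS. Nos2 and Tnf were lower in knockout cells both untreated and with LPS, so their larger folds started from lower resting levels and reached no higher level. Anti-inflammatory mediators had 5 lower responses and 9 not passing (adjusted p = 0.156), Etv3 (-2.25 ± 0.22) among the former. Of the AP-1 family, Batf3 (-1.69 ± 0.32) and Atf3 (-1.41 ± 0.18) responded less (3 lower, 9 not passing; adjusted p = 0.150). The other lower value, that of Junb, is no measured response, because the deleted gene lies at the floor on all 7 knockout arrays. Jund (0.51), Batf (-0.44), Fos (-0.36), Fosb (0.29), Fosl1 (-0.28), Jdp2 (-0.24), Batf2 (0.17), Fosl2 (-0.10, another probe 1.11) and Jun (-0.05) did not pass, with adjusted p of 0.229 or more. Co-stimulatory ligands had 1 higher and 2 lower responses (adjusted p = 0.711). Cd86 differed by -1.37 ± 0.22. NF-kB genes had 2 higher responses (adjusted p = 0.309), the cell cycle 4 lower ones (adjusted p = 0.711), Mcm6 (-1.33 ± 0.24) among them, and the stress response 2 lower ones (adjusted p = 0.995), Ddit4 (-2.29 ± 0.23) among them. Lyz2 has no readable difference, as its wild type signal lies at the bright end, Arg1 at -0.75 ± 0.34 did not pass (adjusted p = 0.195), and Ifnb1 at -0.79 ± 0.22 has no settled direction, since a lower floor gave 0.80. Median, mean and test differed in sign for classical activation, cholesterol biosynthesis, LXR targets, the stress response, NRF2 targets, neutrophil and stromal markers.

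In all, 1432 of 14197 genes differed in their LPS response, 1018 with a lower and 414 with a higher response in knockout cells (460 and 189 by at least 2-fold). Of the 2351 genes induced at least 2-fold on average over both genotypes, 343 had a smaller response in knockout cells, 14.6% (exact 95% interval 13.2% to 16.1%, with genes not independent), and 145 a larger one; at least 4-fold induction gave 18.0%. Of 2072 repressed genes, 171 (8.25%) had a lower value, which is a stronger fall in knockout than in wild type cells, and 72 (3.47%) a higher one. Lower values thus outnumbered higher ones among induced, repressed and all called genes alike. The excess among induced genes therefore does not by itself show weaker induction. The count moved by over 1.5 times with normexp (812), the deposited value table (527 of 11899 genes), array weights (4724), without LPS-treated knockout replicate 3 (932) and without the 3 wide-spread arrays, an alternative chosen after seeing the data (2230).

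In the resting state, knockout macrophages had lower levels of 21 of 29 interferon-stimulated, 12 of 19 chemokine and 6 of 9 MHC class II genes and higher levels of 14 of 24 cell cycle genes than wild type macrophages. None of the 27 lists passed with an estimated correlation. Of 29 interferon-stimulated genes, 21 were lower and none higher (24 adjusted over the list alone; adjusted p = 1.0e-17, but adjusted p = 0.119 with an estimated correlation). Isg15 was at a log2 difference of -2.19 ± 0.17 (another probe -1.59) and the interferon-induced protease Usp18 at -2.08 ± 0.21. Of 19 chemokines, 12 were lower and 1 higher (13 over the list alone; adjusted p = 9.1e-06, adjusted p = 0.119 with an estimated correlation). Cxcl10 was at -2.29 ± 0.26, Ccl12 at -1.69 ± 0.20 (measured on 2 of 4 knockout arrays) and Cx3cl1 at 2.89 ± 0.14. Of 9 MHC class II genes, 6 were lower (6 over the list alone; adjusted p = 0.000239, adjusted p = 0.125 with an estimated correlation). Cd74 was at -1.49 ± 0.20 and H2-Aa at -0.80 ± 0.17. Of 24 cell cycle genes, 14 were higher (15 over the list alone; adjusted p = 2.7e-06, adjusted p = 0.119 with an estimated correlation). The ribonucleotide reductase gene Rrm2 was at 1.39 ± 0.18 and cyclin A2, Ccna2, at 1.36 ± 0.11. Of 11 neutrophil markers, 4 were lower on the same arrays (5 over the list alone; adjusted p = 0.000629, adjusted p = 0.119 with an estimated correlation). The collagenase gene Mmp8 was at -1.50 ± 0.17, and S100a9, well above background on no knockout array, was at least 16.7-fold lower.

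Other lists that passed in untreated cells pointed down. Pro-inflammatory cytokines had 5 lower, 1 higher and 13 not passing (8 over the list alone; adjusted p = 0.00726, adjusted p = 0.119 with an estimated correlation; median -0.12, and 0.02 with normexp). Tnf was at -1.30 ± 0.16 and Tnfsf9 at -1.02 ± 0.13 but Il1b at 0.68 ± 0.21. NF-kB genes had 3 lower and 16 not passing (3 over the list alone; adjusted p = 0.0238, adjusted p = 0.340 with an estimated correlation). Tnip1 was at -0.69 ± 0.14 (another probe -0.16). Classical activation effectors had 6 lower, 2 higher and 16 not passing (11 over the list alone; adjusted p = 0.00211, adjusted p = 0.355 with an estimated correlation). Nos2 was at -2.66 ± 0.18, Saa3 at -1.67 ± 0.20 and the scavenger receptor Marco at 1.43 ± 0.13. Glycolysis had 4 lower, 2 higher and 12 not passing (8 over the list alone; adjusted p = 0.0145, adjusted p = 0.493 with an estimated correlation). Hk3 was at -0.73 ± 0.16 and Hk2 at 0.56 ± 0.13. Cholesterol biosynthesis had 4 lower and 16 not passing (5 over the list alone; adjusted p = 0.000658, adjusted p = 0.355 with an estimated correlation). Dhcr7 was at -1.09 ± 0.16 and Mvd at -1.08 ± 0.17. Macrophage identity had 4 lower, 2 higher and 13 not passing (7 over the list alone; adjusted p = 0.0261, adjusted p = 0.493 with an estimated correlation). Lyz2, which carries Cre, and Lyz1, whose probe is uncertain, are among those lower. The list median was -0.19, and the list was not tested without them, so its direction may rest on Lyz2 and Lyz1. The efferocytosis receptor Mertk was at 1.21 ± 0.18.

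The AP-1 family did not pass (3 higher, 2 lower, 7 not passing; adjusted p = 0.703). Batf (1.27 ± 0.15), Batf3 (1.17 ± 0.22) and Fos (0.56 ± 0.13) were higher and Batf2 (-0.98 ± 0.21) was lower beside Junb, while Jund (0.56), Jdp2 (-0.43), Fosl1 (0.42), Jun (0.36), Atf3 (-0.33), Fosl2 (-0.21, another probe -1.44) and Fosb (-0.06) did not pass. Il10 was higher by 1.63 ± 0.13, and Il6 at 0.47 ± 0.36 did not pass. Ifnb1 was lower and well above background on no knockout array. Alternative activation markers were 6 higher, 6 lower and 10 not passing (adjusted p = 0.682). The mannose receptor Mrc1 was at 1.75 ± 0.14 and Arg1 at -2.88 ± 0.23. Anti-inflammatory mediators were 3 higher and 3 lower (adjusted p = 0.173). Etv3 was at 1.26 ± 0.15 and Il1rn at -1.52 ± 0.20. Co-stimulatory ligands were 3 higher and 1 lower (adjusted p = 0.332). Havcr2 was at 1.97 ± 0.15.

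Large single differences in untreated cells were on the Y chromosome, where Eif2s3y was at least 1238-fold and Ddx3y at least 411-fold higher in knockout cells, and on X, where Xist, the noncoding RNA of X inactivation, was at least 21.9-fold lower. The tumour necrosis factor receptor family members Tnfrsf26 and Tnfrsf23 were at least 176-fold and 102-fold higher. Tspan32 (6.19 ± 0.14, measured on 2 of 4 wild type arrays), Trim12a (5.56 ± 0.21, on 3 of 4), the tetraspanin Cd81 (4.23 ± 0.17), Cd55b (3.92 ± 0.12) and Epb41l3 (3.79 ± 0.16) were also higher. Other probes gave smaller log2 differences: 1.13 for Tnfrsf23, 2.88 and 0.47 for Tspan32, 2.86 for Trim12a and 0.55 for Cd55b, so the sizes of these differences depend on the probe. After Lyz2 and Junb, lower genes included Gdpd3 (-5.16 ± 0.14), the inhibitory Fc receptor Fcgr2b (-2.92 ± 0.14) and Hhipl1 (-2.84 ± 0.23, measured on 1 of 4 knockout arrays). In all, 1688 of 14197 genes were higher and 828 lower (2516 called; 619 by at least 2-fold), 100 of them on X or Y. Median, mean and test differed in sign for the AP-1 family, Toll-like receptors, LXR targets, the stress response, NRF2 targets and stromal markers. Slide and genotype cannot be told apart here, and by Xist, Eif2s3y and Ddx3y the sex of the cells probably differs as well. The count was 1631 with normexp, 1166 in the deposited value table and 5473 with array weights.

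With LPS, knockout macrophages had lower levels of 11 of 19 pro-inflammatory cytokine, 8 of 14 anti-inflammatory and 7 of 9 MHC class II genes and higher levels of 8 of 24 cell cycle genes than wild type macrophages. None of the 27 lists passed with an estimated correlation. Of 19 pro-inflammatory cytokines, 11 were lower and 1 higher (13 over the list alone; adjusted p = 0.000960, adjusted p = 0.1001 with an estimated correlation). Lif was at a log2 difference of -3.84 ± 0.62 (measured on 1 of 3 knockout arrays), Osm at -2.87 ± 0.21, Ifnb1 at -1.39 ± 0.16 and Tnf at -0.51 ± 0.17, while no difference can be read for Il1b and Il6, whose signals with LPS were nearly constant. Of 14 anti-inflammatory mediators, 8 were lower (8 over the list alone; adjusted p = 0.00139, adjusted p = 0.304 with an estimated correlation). Il10 was at -2.46 ± 0.14 and Il1rn at -1.68 ± 0.24. Of 24 classical activation effectors, 11 were lower and 2 higher (14 over the list alone; adjusted p = 0.0328, adjusted p = 0.871 with an estimated correlation). The activin subunit Inhba was at -3.36 ± 0.19, the endothelin precursor Edn1 at -2.43 ± 0.09, Nos2 at -0.63 ± 0.19 and Marco at 1.85 ± 0.15. Of 9 MHC class II genes, 7 were lower (7 over the list alone; adjusted p = 0.00380, adjusted p = 0.304 with an estimated correlation). Cd74 was at -1.87 ± 0.22 and H2-Aa at -1.43 ± 0.18. Of 24 cell cycle genes, 8 were higher and 1 lower (10 over the list alone; adjusted p = 0.00380, adjusted p = 0.304 with an estimated correlation). Ccne1 was at 1.10 ± 0.15 (another probe 0.62) and Mcm6 at -0.69 ± 0.18. Of 11 neutrophil markers, 6 were lower and 1 higher on the same arrays (7 over the list alone; adjusted p = 0.0292, adjusted p = 0.304 with an estimated correlation). S100a9 was at least 22.6-fold lower and Mmp8 at -2.13 ± 0.19.

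Interferon-stimulated genes were 6 lower and 23 not passing with LPS (adjusted p = 0.0693). Irf7 was at -1.72 ± 0.23 and Oas3 at -1.29 ± 0.22. Chemokines were 3 higher, 6 lower and 10 not passing (adjusted p = 0.767). Cx3cl1 was at 4.43 ± 0.15 and Ccl22 at 2.39 ± 0.16 but Ccl12 at -1.43 ± 0.21 and Ccl7 at -1.38 ± 0.19, while no difference can be read for Cxcl10, whose signal with LPS was nearly constant. Alternative activation markers were 8 higher, 6 lower and 8 not passing (adjusted p = 0.381). Ccl17 was at 2.20 ± 0.13, Arg1 at -3.64 ± 0.25 and Socs2 at -1.24 ± 0.14. In the AP-1 family (2 higher, 4 lower, 6 not passing; adjusted p = 0.373), Jund (1.08 ± 0.21) and Batf (0.83 ± 0.16) were higher and Atf3 (-1.74 ± 0.13), Batf2 (-0.81 ± 0.22) and Jdp2 (-0.67 ± 0.16) lower beside Junb, and Batf3 (-0.52), Jun (0.31), Fosl2 (-0.31), Fosb (0.23), Fos (0.19) and Fosl1 (0.15) did not pass. The stress-response gene Ddit4 was at -2.22 ± 0.17 and Slc7a11 at -1.60 ± 0.18 (list 3 higher, 2 lower; adjusted p = 0.846).

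Among single genes, Eif2s3y and Ddx3y were at least 1616-fold and 324-fold higher and Xist at least 53.0-fold lower (another probe -3.79 on the log2 scale) in LPS-treated knockout cells. Trim12a (5.86 ± 0.23), Cd81 (4.04 ± 0.18) and the tubulin gene Tubb2b (3.84 ± 0.17) were higher, as was Tspan32 (3.70 ± 0.14), other probes of which gave 0.58 and -0.24. Gdpd3 (-6.08 ± 0.15), Csta2 (-4.41 ± 0.17), Slc28a2b (-3.78 ± 0.14, another probe -2.83) and Gcnt2 (-3.63 ± 0.22, measured on 2 of 3 knockout arrays) were lower. In all, 1936 of 14198 genes were higher and 2431 lower (4367 called; 1244 by at least 2-fold), 142 of them on X or Y. Of the genes higher untreated, 784 were also higher with LPS, where independent lists would share 230, and of those lower, 494 were also lower, against 142; these comparisons share no array. Median, mean and test differed in sign for chemokines, NF-kB genes, co-stimulatory ligands, NRF2 targets, macrophage identity, dendritic cell and erythroid markers. Slide, probable sex and genotype cannot be told apart here, and the count was 2588 in the deposited value table and 2869 without LPS-treated knockout replicate 3.

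Genes beside an engineered locus can carry DNA of another strain. Of 207 tested genes within 10 Mb of Junb or Lyz2, 33 were called untreated (15.9%, against 17.7% elsewhere; two-sided Fisher exact p = 0.582) and 54 with LPS (26.1%, against 30.8%; p = 0.150).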

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

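Of the tests in this part, that of a constant offset between the slides was chosen only after the result was seen. A rule for a sample far from the others of its group was applied to 55 groups of values and marked 7, where chance marks about 1 in 20 groups, or 2.75 of 55. Junb had a log2 signal of 3.71 in LPS-treated wild type replicate 2, against 3.08 to 3.17 in the other replicates. Il1b was 2.83 in untreated wild type replicate 1, against 3.56 to 3.57, and the mean of the chemokine genes on that array was 0.42, against 0.76 to 0.83. Arg1 was -1.08 in untreated knockout replicate 2, against -1.59 to -1.52, and the mean of the cell cycle genes was -0.19 in untreated knockout replicate 3, against 0.19 to 0.27. Spots marked as outliers by the scanner software numbered 2115 on untreated knockout replicate 3, against 170 to 183 in its group, and 133 on LPS-treated wild type replicate 2, against 155 to 158.

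Differences between the genotypes in the LPS response of the genes followed throughout were -2.54 for Junb, 1.28 for Lyz2, 0.78 for Tnf, -4.10 for Il10, 2.03 for Nos2, 2.35 for Cxcl10 and -0.79 for Ifnb1, the last without a settled direction, and 1432 genes differed in all. The value of Junb is the wild type rise set against a floor, and that of Cxcl10 reflects untreated levels, since its signal with LPS was nearly constant. The value of Lyz2 is no measured difference either, because its wild type signal lies at the bright end of the arrays. Nos2 and Tnf were lower in knockout cells both untreated and with LPS, so their positive values mark a larger fold and not a higher level. A signal also lies in probes that got no symbol here: 6223 of 14177 such probes were called for LPS in wild type cells, 4372 higher and 1851 lower.

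Interferon-stimulated genes were lower in untreated knockout cells and nearer to wild type with LPS: the mean of the 29 genes differed by -1.02 ± 0.14 (SE) untreated and -0.32 ± 0.16 with LPS. A constant offset between the slides would give the same difference in both. The differences differ by 0.70 (95% interval 0.23 to 1.17), but this restates the observation and includes bright genes such as Rsad2, so such an offset remains open. Compression of bright signals could not be told apart: among the 14 dimmer genes the median difference of response was 0.18, with a lower limit of -0.04, and 10 of 14 were positive, against a median of 0.86 among the brighter genes. General activation of the untreated wild type wells may also contribute. The median fall of cytokine and NF-kB genes in untreated knockout cells was 6.81% of their wild type LPS response. For interferon-stimulated genes the median was 23.2%. The 95% interval of the former (2.68% to 12.9%) comes from resampling its genes, so it does not measure the spread between wells. These values do not settle whether such activation contributes. An effect of the genotype remains open, as slide and genotype coincide.

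Other splits of the same arrays into groups of the same sizes tested whether the counts of called genes exceed those of arbitrary groups. For LPS in wild type cells 1 of 35 splits, the real one, called as many as 8583 genes, and the highest other split called 73. For LPS in knockout cells it was 1 of 35 (8510), with 5523 in the highest other split, and for knockout against wild type 1 of 35 untreated (2516, highest other 292) and 1 of 35 with LPS (4367, highest other 2112). The splits with 5523 and 2112 genes give most of the arrays compared the other group's label. They are thus close to the real groupings with the sign reversed, and are not arbitrary groups. For the difference of the LPS responses, 2 of 100 splits called at least 1432 genes, the real one included, and the highest other called 2762; that split exchanges most genotype labels among untreated arrays and keeps those of the LPS arrays, so it adds genotype differences that the real contrast subtracts.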

How the results depend on the processing

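The counts of called genes and the direction of the main gene results depended on the processing to different degrees. Of 135 list results, 82 stayed on the same side of the threshold under every setting they were run in and 0 reversed; of 468 gene results, 347 stayed. The filter on all 15 arrays covered 125 lists and 352 genes, and 377 genes were in the value table. The LPS counts ranged from 8001 to 8754 in wild type and 7663 to 8802 in knockout cells with each replicate left out, and requiring at least 2-fold gave 4539 and 4499. The difference count of 1432 became 812 with normexp, 527 in the deposited value table, 4724 with array weights, 649 at 2-fold, 932 without LPS-treated knockout replicate 3 and 1935 without untreated wild type replicate 4; it was 2230 without the 3 wide-spread arrays, which was chosen after seeing the data. Knockout against wild type untreated (2516) became 1631 with normexp, 1166 in the value table, 5473 with array weights and 619 at 2-fold, and ranged from 1728 to 2875 with replicates left out. With LPS (4367) it became 2588 in the value table and 1244 at 2-fold, and ranged from 2869 (without LPS-treated knockout replicate 3) to 4957 (without untreated wild type replicate 1). Leaving out X and Y, chosen after seeing the data, gave 2415 and 4226. Of 47 list tests called, 10 remained with an estimated correlation. The correlation of the LPS responses was 0.842 in the value table and 0.860 (without LPS-treated wild type replicate 4) to 0.906 (without LPS-treated knockout replicate 3), and the share of induced genes with a smaller response was 18.0% at 4-fold. The value table tests fewer genes (11899) and also differs in signal and normalisation, and the cause was not tested for any of these settings. With replicate number as a block the 5 counts were 8441, 8386, 1118, 2204 and 3992; over 7 pairs the correlations ran from -0.53 to 0.56, with 3 over 0.1, so the numbers do not pair samples.

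Some genes took the other direction. For LPS in wild type cells these were H2-DMb1 (-0.96), Srebf1 (-0.092), Atp5b (-0.073) and Cox7a2 (-0.23) in the value table, Jund (-0.094), Atp5b (-0.033) and Cox7a2 (-0.18) under quantile normalisation, Tfrc (0.079) with the mean of probes and Cd80 (2.03) with every probe tested. For LPS in knockout cells they were Cox7a2 (-0.081) and Blnk (-0.13) under quantile normalisation, and Cox7a2 (-0.068) and Tlr13 (0.45) in the value table, with Tlr13 at 0.40 when outlier spots were kept. For the difference they were Irak4 (0.010) and Cd83 (0.56) in the value table and Ifnb1 (0.80) with the lower floor, chosen after seeing the data. With that floor the difference of Car2 kept its direction but did not pass. For knockout against wild type untreated they were Gclm (-0.99) and Tlr13 (-1.75) in the value table, Tlr13 (-1.01) and Pfkfb3 (-0.12) with outlier spots kept, and Pfkfb3 (-0.43) with the mean of probes. The cause was not tested, and with 51.0% to 63.2% of spots well above background, dim genes are the ones that signal strength limits.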

Other observations

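Of the tests in this part, those of other chromosome segments, of the sex of the mice by sex-linked genes and of swapped labels were chosen only after the result was seen. Among lists not described so far, LPS moved osteoclast markers both ways in wild type cells (5 rose, 3 fell, 2 did not pass; adjusted p = 0.639), with the acid phosphatase Acp5 at 2.39 ± 0.13 and the transcription factor Nfatc1 at -1.84 ± 0.19 (another probe -0.85). Acp5 rose more in knockout cells (difference 0.79 ± 0.19), and the protease Ctsk was lower there both untreated (-1.60 ± 0.14) and with LPS (-1.39 ± 0.15). Cholesterol efflux and LXR targets had 1 rise and 4 falls (adjusted p = 0.214), with the desaturase Scd2 at -4.25 ± 0.13. NRF2 targets had 4 rises and 3 falls (adjusted p = 0.939), with the thioredoxin reductase Txnrd1 at 1.30 ± 0.13 and Nqo1 at -1.12 ± 0.15.

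Stromal markers had 7 rises and 0 falls in wild type cells (adjusted p = 0.0820); the growth factor receptor Pdgfrb rose by 3.91 ± 0.15 in wild type and 6.14 ± 0.16 in knockout cells, a difference of 2.22 ± 0.22. T and NK cell markers had 3 rises and 1 fall (adjusted p = 0.627), with the kinase Lck at 3.81 ± 0.19 and Cd5 at -1.21 ± 0.13, and mast cell and basophil markers had 2 rises (adjusted p = 0.0688). Oxidative phosphorylation genes show how far the scaling matters: 7 rose and 1 fell with LPS in wild type cells, but under quantile normalisation 0 rose and 22 fell, and the list median went from 0.090 to -0.57.

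The set of 50 genes called in both comparisons of knockout with wild type, in the same direction and at least 4-fold in each, holds 29 higher and 21 lower genes. DNA of another strain within 10 Mb of Junb or Lyz2 is excluded as the main source, as 8% of the set (4 genes, upper 95% limit 19.2%) lies there. These 4 genes include Junb and Lyz2 themselves, and longer stretches were not tested for this set. Genes on X or Y make up 16% of the set (8 genes, upper limit 29.1%), so they are not its main part. A different sex of the mice could also alter genes of other chromosomes, so this share cannot exclude it. DNA of another strain at other chromosome segments may contribute: a 10 Mb window holds up to 5 set genes, a number reached by 72 of 10000 random sets (median 3, 95th percentile 4), while an equally large set of the strongest LPS responses reached 4. The densest window, on chromosome 3, holds Fcrls, Cd5l, a clone-named gene, S100a9 and Tmod4, and another on chromosome 7 holds Tspan32, Cd81, Tnfrsf26 and Tnfrsf23; other probes of Tspan32 and Tnfrsf23 gave smaller differences, these genes were picked out after their values were seen, the hypothesis arose from their names, and related genes can also lie together for other reasons.

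Sex-linked genes differed between the genotypes. If wild type cells came from females and knockout cells from males, all 5 measured genes should separate the genotypes on every array; 4 of the 5 did so, with log2 gaps of 3.29 for Xist, 7.51 for Ddx3y, 9.35 for Eif2s3y and 1.26 for Uty, while Kdm5d overlapped, so the test could not tell. This test was revised after its result was seen; its stricter first form, by background flags, was met by 8 of 15 arrays (7 of 7 knockout and 1 of 8 wild type). A pair of sample labels swapped between the genotypes is excluded, since 0 arrays showed the pattern of the other genotype. Labels swapped within a genotype cannot be seen in sex-linked genes and were not tested here. Xist was well above background on 8 of 8 wild type and 0 of 7 knockout arrays, and Ddx3y and Eif2s3y on 0 of 8 and 7 of 7. Uty and Kdm5d were well above background on 6 and 5 of the wild type arrays too. Xist, Ddx3y and Eif2s3y argue against the same sex in both genotypes. Sex and genotype therefore probably coincide and cannot be told apart. Genes of X and Y made up 3.97% of the calls untreated and 3.25% with LPS.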
